A study of Mus musculus with 768 samples.

How the data were processed

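Single-cell RNA sequencing was done on 768 mouse ES-E14TG2a embryonic stem cells. There were 48 cells for each of 2 genotypes (WT and TKO), 4 days (Day 0, 1, 2 and 4) and 2 batches. Libraries followed the SMART-seq2 protocol, which copies full-length messenger RNA of sorted cells without molecular identifiers, and were read as paired ends of 50 bp. Cells were taken from a medium that holds the naive state and moved to one with Fgf2 and Activin A, in which they become epiblast-like cells. The group of each cell was taken from its title, because the genotype field gives WT for every cell. The labels do not name the genes disrupted in TKO; from what is known of the study, TKO is the knockout of the 3 active DNA methyltransferases. The labels name batches but do not say that these were separate cultures, so p-values of tests across genes measure only the spread between these batches.

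The authors deposited, for each cell, a table of raw read counts per gene, whole numbers that had not been normalised. Per the submitters' processing notes, Trim Galore 0.6.5, STAR 2.7.5a and featureCounts 1.5.1 were used, with the mm10 and GRCm38 builds. The annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Members of families with near-identical copies (Rhox, Xlr, Tuba3a, Rpl10l, Rpl39l, Gbp2 and Gbp2b) are therefore uncertain, as are genes that overlap others. Each table held 55383 features, of which 92 were spike-in controls and 55291 were genes, 37 of them mitochondrial. Positions come from GENCODE M21 on GRCm38, matched by symbol; 22966 of the 23630 tested genes (97.2%) had exactly 1 gene of that symbol there.

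Cells were kept with at least 50000 reads on genes, at least 2000 genes and at most 20% mitochondrial reads. The filter kept 704 cells, 359 WT and 345 TKO; all 64 left out had too few reads, the deepest having 46754. Spike-in reads were left out of the library sizes. Doublets were not called, because cells were sorted one by one into wells. Counts were summed over the kept cells of each genotype, day and batch, which gave 16 sums of 40 to 48 cells and 16452604 to 49453688 reads. A sum is the replicate in all tests across genes, with n = 2 batches per group. CPM of a sum is reads of a gene for every 1e6 reads on the tested genes, after the TMM scaling of the fit. CPM of a cell is per 1e6 reads of that cell on genes. Errors on CPM are SD over these 2 sums. Errors on log2 folds, marked SE, are the absolute log2 fold divided by the square root of its quasi-likelihood F. They are approximate standard errors derived from the test and can differ from the spread of the 2 sums.

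The sums were fitted in one edgeR (4.0.16, R 4.3.3) quasi-likelihood model with 8 genotype-by-day groups and a batch term, TMM scaling and the edgeR filter on low counts. The model had 7 residual degrees of freedom and a common biological coefficient of variation of 0.300. Adjusted p-values are Benjamini-Hochberg values over the 23630 genes, with a threshold of 0.05. Contrasts were TKO against WT on each day and over the mean of the days, Day 4 against Day 0 in each genotype, any day against Day 0, and the difference of the time courses. The batch number is a batch name in the labels, so it was kept as a block. As a check, same-numbered sums deviated from their group means together in all 28 pairs of groups, with r across genes from 0.0277 to 0.279. The fit was tested on simulated Day 4 data, with 200 of 23630 genes changed, all from genes at a mean of 5 CPM or more. It recovered 59.0% of genes changed by 2-fold and 94.0% of those changed by 4-fold, and 6.13% of its calls were false. DESeq2 (1.42.0) recovered 85.5% of all changed genes on the same data, with 20.5% of its calls false. The sign-flip test called 4.5% of simulated sets without a difference.

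Before the data were examined, 24 gene lists were fixed. They covered naive, formative and core pluripotency, germline genes silenced by promoter methylation, primordial germ cell specification, neural, mesendoderm, primitive endoderm, trophoblast and two-cell-like genes, X-linked homeobox and Xlr clusters, imprinted genes, the DNA methylation machinery, FGF-ERK, WNT and Activin-Nodal targets, glycolysis, oxidative phosphorylation, p53 targets, S phase, G2 and M phase, dissociation and heat stress, fibroblast genes, and interferon genes. Lists were tested with camera in limma (3.58.1) at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 192 tests of 24 lists and 8 contrasts. Across all 192 tests, the ones past the threshold with an estimated correlation numbered 22. Some genes stand in more than 1 list.

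Genes are named by a rule also fixed beforehand. It takes the 8 largest changes in each direction among genes past the threshold with the same sign in both batches and at least 5 CPM in the higher group, without predicted genes and clones. It adds from each list up to 4 members past the threshold with the smallest p and the best expressed member that was not, and the 8 genes with the smallest p for the difference of the time courses. Genes named outside it are marked as chosen after their values were seen. A fold against a group without reads is given as a lower bound from a floor of 3 reads over the group, and one against 1 to 3 reads as a ratio with an exact 95% counting interval. Reads are not independent molecules here, so these floors and intervals, and the Wilson intervals on shares of cells, cover counting error only.

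Per-cell measures used cells thinned to 50000 reads, with log2(CPM + 1). The list position score is the mean over the formative list minus the mean over the naive list. Each cell was also assigned to the WT day whose mean profile in the other batch it resembled most by rank correlation over 500 genes. TKO and WT means were compared over the 8 day-by-batch pairs with a two-sided exact sign-flip permutation test. Its smallest possible p is 0.00781, and the 4 pairs of 1 batch cannot go below 0.125. The 8 pairs are 4 days of the same 2 batches and of 1 line per genotype. The test treats them as independent, which the labels do not show. The alternatives were other scalings, filters on genes and cells, DESeq2, limma on the mean over cells of log2(CPM + 1), thinned sums, no batch term, each batch alone, and leaving out each sum in turn. A gene past the threshold neither in the main result nor in an alternative was counted as unchanged by it. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.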

Results

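Expression was compared between WT cells and TKO cells as they left the naive state of mouse embryonic stem cells and became epiblast-like, over Day 0, 1, 2 and 4. Each of the 8 groups held 2 batches of 48 cells, and 40 to 48 cells per group and batch were kept. A kept cell had a median of 795622.5 reads and 12283 detected genes, with 53680 to 1550862 reads. The median cell had 1.06% of its reads on mitochondrial genes, and the highest 3.53%. Reads per sum ranged from 16452604 (TKO Day 0, batch 1) to 49453688 (TKO Day 1, batch 1).

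The knocked-out genes were examined first, since the genotype rests on the cell titles. Dnmt1, the maintenance methyltransferase (chromosome 9, 20907209 to 20959888), stood at 65.9 ± 7.54 CPM in TKO and 307 ± 25.9 CPM in WT at Day 0, a log2 change of -2.22 ± 0.11 (SE, n = 2; adjusted p = 8.52e-06). The de novo methyltransferase Dnmt3a (chromosome 12, 3806007 to 3914443) was changed by -2.45 ± 0.23 at Day 0 and -3.62 ± 0.20 at Day 4. Dnmt3b (chromosome 2, 153649450 to 153687730), the other de novo enzyme, was changed by -3.14 ± 0.41 at Day 0 and -3.45 ± 0.31 at Day 4, when it reached 93.6 ± 20.1 CPM in TKO against 1022 ± 134 CPM in WT. These 3 genes were past the threshold on all 4 days, with adjusted p-values up to 0.0358. Reads outside a deleted part check nothing, and the deleted parts are not given in the sources used here. Tet1, Tet2, Tet3 and Tdg, which act in demethylation, were not past the threshold on any day; Tet1 stood at 382 ± 5.80 CPM in TKO and 462 ± 21.7 CPM in WT at Day 4 (adjusted p = 0.138).

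**Figure D1:**
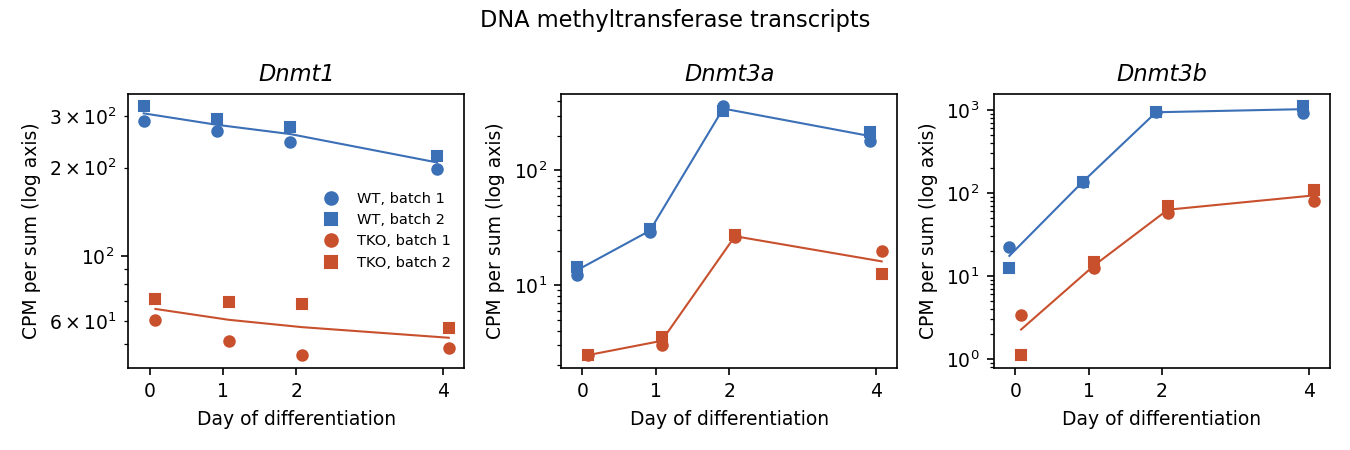
CPM of Dnmt1, Dnmt3a and Dnmt3b (log axes) in each sum against the day of differentiation, for WT (blue) and TKO (red), with batch 1 as circles and batch 2 as squares and lines through the means. Every TKO sum lies below both WT sums of its day for all 3 genes, as for Dnmt1 at Day 0 with means of 65.9 and 307 CPM.

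The WT time course gives the course of differentiation against which TKO is set. Between Day 0 and Day 4, Tfcp2l1, a transcription factor of the naive state, fell from 1249 ± 108 to 8.42 ± 0.219 CPM (log2 -7.21 ± 0.27, n = 2). Klf4 and Klf5, further factors of that state, changed by -5.95 ± 0.26 and -3.13 ± 0.15, and Tcl1, a cofactor of AKT, by -6.44 ± 0.40. Otx2, a regulator of the formative state, rose from 11.0 ± 3.34 to 304 ± 26.9 CPM (4.83 ± 0.23), and Pou3f1, a POU factor of the epiblast, by 7.89 ± 0.46. Of the naive list, 2 genes rose and 23 fell out of 27 (camera adjusted p = 1.49e-24). Of the formative list, 20 rose and 0 fell out of 25 (camera adjusted p = 7.65e-30). Both list calls held with an estimated correlation (adjusted p = 0.0204 and 0.0190). Of the core pluripotency list, 5 rose and 2 fell out of 10 (adjusted p = 1.98e-04, and 0.0751 with an estimated correlation): Utf1, a chromatin factor, rose by 4.50 ± 0.10 and Lin28a, a repressor of let-7, by 6.01 ± 0.30, while Sox2 changed by -1.36 ± 0.13. Over all genes tested by edgeR quasi-likelihood with Benjamini-Hochberg adjustment, 7809 differed at Day 4, 3821 higher and 3988 lower. Already 3070 differed at Day 1 and 6321 at Day 2, and 9653 differed over any day.

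Signalling and metabolic genes moved in the same WT interval. Of the FGF-ERK targets, 9 of 16 rose and 0 fell (adjusted p = 6.47e-09, and 0.0365 with an estimated correlation); the ERK phosphatases Dusp4 and Dusp6 rose by 8.23 ± 0.44 and 4.88 ± 0.27 and the feedback inhibitor Spry4 by 4.25 ± 0.34. WNT targets included 2 that rose and 7 that fell out of 15 (adjusted p = 0.0149, and 0.309 with an estimated correlation). Axin2, a feedback inhibitor of WNT signalling, changed by -3.19 ± 0.33, and Sp5 had 4375 reads at Day 0 and 1 at Day 4, a ratio of 3955 (709 to 156234). Activin-Nodal targets had 6 genes up and 1 down out of 13 (adjusted p = 0.00526, and 0.0741 with an estimated correlation), with Lefty1, a Nodal inhibitor, at 6.39 ± 0.52 and Skil at 3.10 ± 0.21. Glycolysis genes rose, 13 up and 4 down out of 18 (adjusted p = 9.26e-15, and 0.0204 with an estimated correlation). Among them were the glucose transporter Slc2a1 at 3.25 ± 0.12, Pgk1 at 2.10 ± 0.08 and pyruvate kinase Pkm at 1.89 ± 0.06. Of the oxidative phosphorylation genes, 12 of 25 fell and 0 rose (adjusted p = 0.00823, and 0.479 with an estimated correlation), with Cox5a at -1.28 ± 0.08.

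Germline, X-linked and imprinted genes changed as well in WT. The germline list had 10 genes up and 15 down out of 44 (adjusted p = 0.00186, and 0.197 with an estimated correlation); Dazl, an RNA-binding protein of germ cells, changed by -5.53 ± 0.35, Fkbp6, a co-chaperone of meiosis, by -4.21 ± 0.25 and Rpl10l, a testis paralog of a ribosomal protein, by -4.65 ± 0.16. In the X-linked homeobox and Xlr list, 19 of 23 genes fell and 0 rose (adjusted p = 1.48e-06, and 0.0397 with an estimated correlation), Rhox2a by -4.81 ± 0.56. Imprinted genes had 16 up and 6 down out of 43 (adjusted p = 0.00115, and 0.196 with an estimated correlation), such as Mest at 2.95 ± 0.13, Zdbf2 at 3.06 ± 0.12 and Plagl1 at -5.41 ± 0.30. In the methylation machinery, 6 rose and 7 fell out of 18 (adjusted p = 0.821). Dnmt3l, a cofactor of the de novo enzymes, rose by 5.65 ± 0.40 and Tet2, a methylcytosine dioxygenase, changed by -3.65 ± 0.23. The largest changes included Vrtn, at least 570-fold higher at Day 4, Has2, a hyaluronan synthase, at least 394-fold higher, and Tnni1, a troponin, at least 591-fold lower. The chemokine gene Cxcl12 had 1 read at Day 0 and 6721 at Day 4, a ratio of 7435 (1334 to 293728.2), and Cdx1, a caudal homeobox gene, 8332 and 2 reads, a ratio of 3766 (1042 to 31099.7).

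TKO cells also left the naive state. Tfcp2l1 fell from 1290.4 ± 107 to 25.8 ± 8.21 CPM (log2 -5.62 ± 0.24, n = 2), Klf4 changed by -5.12 ± 0.24 and Klf5 by -2.57 ± 0.15, while Otx2 rose from 20.2 ± 4.24 to 179 ± 27.9 CPM (3.10 ± 0.21) and Pou3f1 by 7.97 ± 0.47. Of the naive list, 2 genes rose and 22 fell out of 27, and of the formative list, 21 of 25 rose and 0 fell; both calls held with an estimated correlation (adjusted p = 0.0259 and 0.0190). FGF-ERK targets had 9 up and 0 down out of 16 (adjusted p = 9.74e-11) and glycolysis genes 12 up and 4 down out of 18 (adjusted p = 6.45e-10). Both of these held with an estimated correlation (adjusted p = 0.0242 and 0.0360). Dusp4 rose by 7.98 ± 0.45, Slc2a1 by 3.62 ± 0.12 and Dnmt3l by 7.90 ± 0.40. The germline list had 11 up and 9 down out of 44 (adjusted p = 0.780), the X-linked list 1 up and 10 down out of 23 (adjusted p = 0.0177, and 0.214 with an estimated correlation), and the imprinted list 24 up and 4 down out of 43 (adjusted p = 8.88e-06, and 0.0741 with an estimated correlation). Among the largest changes were Car4, a carbonic anhydrase, at least 954-fold higher at Day 4, Psmb8, a subunit of the immunoproteasome, at least 759-fold higher, Bst1 at least 259-fold lower, and Ly6a, a surface antigen, with 4034 reads at Day 0 and 1 at Day 4 (ratio 3511, 630 to 138727.2). In all, 8038 genes differed between Day 4 and Day 0, 4168 higher and 3870 lower. WT and TKO share no libraries in these comparisons. In both, 2923 genes were higher and 2855 were lower, against 674 and 653 for independent lists, and 24 went opposite ways. Across genes, which are not independent replicates, the log2 folds had r = 0.746.

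At Day 0, in the naive state, few genes other than the methyltransferases separated TKO from WT. Glipr2 stood at 4.74 ± 1.20 CPM in TKO and 16.4 ± 4.26 CPM in WT (log2 -1.75 ± 0.23, n = 2; adjusted p = 0.0358), and Akr1b3, an aldose reductase, at 44.2 ± 0.690 and 67.2 ± 4.25 CPM (-0.60 ± 0.08). With the 3 Dnmt genes these made 5 lower genes, and 1 gene, the predicted gene Gm19409 (chosen after its value was seen), was higher. Naive genes stood at similar levels, Tfcp2l1 at 1290.4 ± 107 and 1249 ± 108 CPM (adjusted p = 1). Dazl stood at 243 ± 40.4 and 234 ± 73.1 CPM. The methylation machinery was lower, 3 of 18 (adjusted p = 8.53e-12, and 0.0190 with an estimated correlation), but the 3 are the knocked-out genes themselves. Camera also placed the X-linked list lower (adjusted p = 0.0194) and the p53 targets higher (adjusted p = 0.00134). With an estimated correlation neither call held (adjusted p = 0.220 and 0.389), and no single member was past the threshold. The count of 6 genes was 301 with DESeq2 and 2 with library totals alone, both lower.

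At Day 1, only Dnmt1, Dnmt3a and Dnmt3b were past the threshold in edgeR, at -2.22 ± 0.11, -3.19 ± 0.20 and -3.34 ± 0.32 (n = 2). The naive factor Zfp42 stood at 1381 ± 113 CPM in TKO and 1160.0 ± 47.9 CPM in WT (adjusted p = 0.999), and Pou5f1, a core factor, at 717 ± 70.1 and 615 ± 9.19 CPM (adjusted p = 0.615). The dissociation and heat stress list was placed higher in TKO (camera adjusted p = 4.17e-06, and 0.0242 with an estimated correlation). No member passed over all genes, and 3 rose when adjusted over the list alone; its best expressed gene, the chaperone Hsp90aa1, stood at 2315 ± 18.5 and 2166 ± 50.9 CPM. Naive and trophoblast genes were placed higher (adjusted p = 0.0214 and 0.0223), and lost the call with an estimated correlation (adjusted p = 0.476 and 0.151). DESeq2 called 125 genes at Day 1.

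At Day 2, glycolytic enzymes were lower in TKO. Triose phosphate isomerase, Tpi1, stood at 257 ± 4.27 CPM in TKO and 449.7 ± 5.08 CPM in WT (log2 -0.81 ± 0.11, n = 2; adjusted p = 0.0308), Pgk1 was changed by -0.50 ± 0.08, Aldoa by -0.45 ± 0.06 and Pkm by -0.40 ± 0.06. Of the glycolysis list, 4 of 18 fell and 0 rose, and 10 fell and 1 rose when adjusted over the list alone (camera adjusted p = 4.66e-14, and 0.0242 with an estimated correlation). Among the higher genes, the matricellular protein gene Ccn1 stood at 20.0 ± 9.46 and 3.86 ± 1.08 CPM (2.34 ± 0.36), and Cald1, caldesmon, at 72.5 ± 9.23 and 28.0 ± 1.51 CPM (1.36 ± 0.17). Plekhb2 rose by 1.81 ± 0.29, Mbnl2, a splicing factor, by 1.29 ± 0.19 and Mme, neprilysin, by 1.13 ± 0.16. Fosb, an immediate early gene, had 48 reads in TKO and 0 in WT, at least 17.6-fold higher. Dnmt3c, a de novo methyltransferase of the male germline with sequence close to Dnmt3b, was changed by -2.68 ± 0.39, and Eif2s3y, a Y-linked initiation factor, by -1.55 ± 0.17. Reads of Y-linked genes were absent from 81 of 345 TKO cells and 17 of 359 WT cells over all days.

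Further lists were also placed higher or lower at Day 2. The methylation machinery was lower, 3 of 18 (adjusted p = 1.23e-11, and 0.0190 with an estimated correlation), the 3 being the knocked-out Dnmt1, Dnmt3a and Dnmt3b. The genotype itself may give this call, and the list was not tested without them. Primitive endoderm genes were placed higher (adjusted p = 3.74e-05, and 0.0242 with an estimated correlation), with 0 of 20 past the threshold over all genes and 1 up adjusted over the list alone. Lamc1, a laminin chain, stood at 267 ± 24.6 and 215 ± 20.1 CPM. The share of cells with at least 4 primitive endoderm genes at 10 CPM was not higher, at 69 of 87 in TKO and 72 of 89 in WT. The fibroblast list was placed higher, 1 up of 12 (adjusted p = 2.45e-04, and 0.0360 with an estimated correlation). Ccn1 was the member past the threshold, and Fbln1, a matrix glycoprotein, stood at 40.0 and 27.2 CPM (adjusted p = 0.214). Naive genes were placed higher and formative genes lower (adjusted p = 2.82e-06 and 7.76e-04), and p53 targets higher (adjusted p = 1.23e-06). None of these 3 held with an estimated correlation (adjusted p = 0.188, 0.220 and 0.212). The remaining lists past the preset test at Day 2 were primordial germ cell and mesendoderm genes, higher, and S phase genes, lower (adjusted p = 0.0103, 0.0159 and 0.0223); none held with an estimated correlation (adjusted p = 0.258, 0.184 and 0.697). In total 29 genes differed, 18 higher and 11 lower, or 19 and 7 with library totals alone. Leaving out any of the 4 Day 2 sums left 3 to 8 genes, the fewest without the TKO sum of batch 2, and DESeq2 called 519.

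At Day 4, the germline list and the X-linked homeobox and Xlr list were placed higher in TKO. Usp26, an X-linked deubiquitinase gene of the testis, had 388 reads in TKO and 0 in WT, at least 139-fold higher. Asz1, a factor of the piRNA pathway, stood at 16.8 ± 3.43 CPM in TKO and 1.22 ± 0.751 CPM in WT (log2 3.86 ± 0.71, n = 2; adjusted p = 0.0236). Rhox2a and Rhox4a, homeobox genes of near-identical families, rose by 3.81 ± 0.55 and 3.27 ± 0.59. The WNT5A receptor gene Ror2 stood at 11.0 ± 1.73 and 1.20 ± 0.317 CPM (3.20 ± 0.25; adjusted p = 1.76e-04). Nab2, a corepressor of EGR factors, rose by 4.10 ± 0.55, Mgl2, a lectin gene, by 3.75 ± 0.47 and Stac2 by 3.26 ± 0.33. Lower in TKO, besides the Dnmt genes and Dnmt3c at -2.97 ± 0.39, were Actc1, cardiac actin, at 1.11 ± 0.0939 and 17.3 ± 0.148 CPM (-3.96 ± 0.65), Sycp3, a protein of the synaptonemal complex, by -2.38 ± 0.45, Rbm47 by -2.28 ± 0.50 and Pdk2, a kinase of pyruvate dehydrogenase, by -1.73 ± 0.35.

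By list, the germline genes at Day 4 included 9 higher and 1 lower of 44, or 11 and 1 adjusted over the list alone (camera adjusted p = 7.58e-11, and 0.0242 with an estimated correlation). Fkbp6 stood at 38.5 ± 2.80 and 9.47 ± 3.85 CPM (2.06 ± 0.23); Sohlh2, a transcription factor of early germ cells, rose by 1.70 ± 0.20, Hormad1, a meiotic chromosome axis protein, by 1.67 ± 0.25 and Tex19.1 by 1.47 ± 0.18. In the X-linked list, 3 of 23 were higher and 0 lower, or 6 and 0 adjusted over the list alone (adjusted p = 9.09e-06, and 0.0397 with an estimated correlation); these were Rhox2a, Rhox1 at 3.04 ± 0.60 and Rhox4b at 4.08 ± 0.91. Of the imprinted genes, 6 of 43 were higher and 0 lower (adjusted p = 0.0137, and 0.299 with an estimated correlation). The growth factor receptor adaptor Grb10 stood at 66.0 ± 5.14 and 11.4 ± 6.02 CPM (2.55 ± 0.29), Peg10 rose by 1.47 ± 0.24, Peg12 by 3.61 ± 0.71 and Peg3 by 0.76 ± 0.13, while Mest stood at 426 ± 32.9 and 492 ± 19.3 CPM (adjusted p = 0.488). Among the methylation machinery 1 was higher and 3, the knocked-out genes, lower of 18 (adjusted p = 4.64e-05, and 0.0567 with an estimated correlation), the higher being Dnmt3l at 73.1 ± 39.0 and 20.9 ± 0.358 CPM (1.76 ± 0.24).

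**Figure D2:**
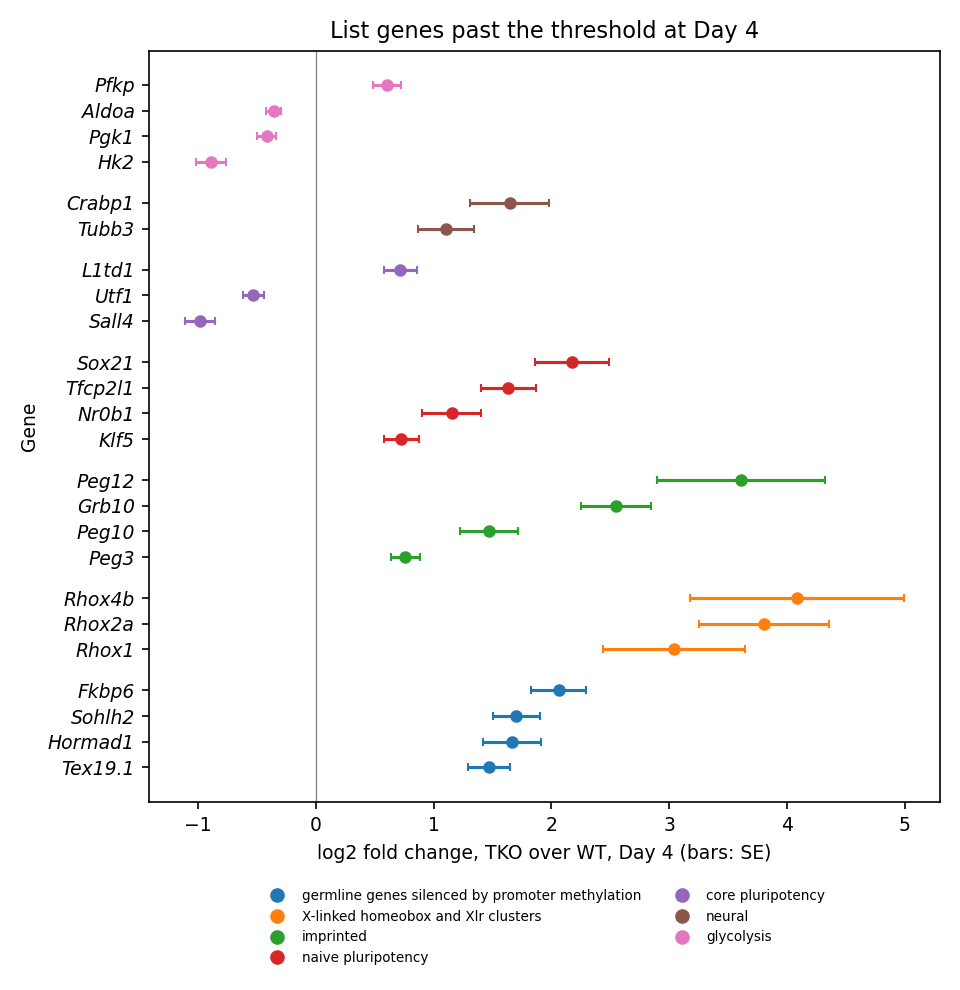
Log2 fold change of TKO over WT at Day 4 (points, with bars of 1 approximate SE derived from the edgeR F-test on 2 batches per group), coloured by list. Shown are, from each of 7 lists, up to 4 members past the threshold with the smallest p. Sycp3, the germline gene past the threshold that was lower, is not among them. Germline, X-linked, imprinted, naive and neural genes shown lie above 0, from 0.73 for Klf5 to 4.08 for Rhox4b, while Sall4, Utf1, Hk2, Pgk1 and Aldoa lie below.

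Pluripotency genes also differed at Day 4. Of the naive list, 4 of 27 were higher in TKO and 0 lower, or 12 and 0 adjusted over the list alone (adjusted p = 4.86e-11, and 0.0741 with an estimated correlation). Tfcp2l1 stood at 25.8 ± 8.21 and 8.42 ± 0.219 CPM (1.63 ± 0.23), and Sox21 rose by 2.17 ± 0.32, Nr0b1 by 1.15 ± 0.25 and Klf5 by 0.73 ± 0.15. Of the formative list, 0 of 25 were past the threshold and 4 fell adjusted over the list alone (adjusted p = 0.00538, and 0.310 with an estimated correlation). The core list had 1 up and 2 down of 10 (adjusted p = 0.0495, and 0.323 with an estimated correlation): Sall4, a zinc finger factor, at -0.98 ± 0.13, Utf1 at -0.53 ± 0.09 and L1td1, an RNA-binding protein, at 0.72 ± 0.14. Neural genes had 2 up of 21 (adjusted p = 0.00271, and 0.130 with an estimated correlation), the retinoic acid binding protein Crabp1 at 1.65 ± 0.34 and tubulin Tubb3 at 1.10 ± 0.24. The germ cell surface gene Ifitm1 rose by 1.25 ± 0.13, as 1 of 15 of its list (adjusted p = 0.0140, and 0.279 with an estimated correlation). Glycolysis genes had 1 up and 6 down of 18 (adjusted p = 1.95e-04, and 0.149 with an estimated correlation), with hexokinase Hk2 at -0.89 ± 0.13, Pgk1 at -0.42 ± 0.08, Aldoa at -0.36 ± 0.06 and phosphofructokinase Pfkp at 0.60 ± 0.12. In the stress list, 1 of 20 rose, the small heat shock protein Hspb1 at 1.20 ± 0.23, or 7 adjusted over the list alone (adjusted p = 0.00302, and 0.0751 with an estimated correlation). In 3 further lists no member was past the threshold: oxidative phosphorylation and G2 and M phase genes were placed lower and p53 targets higher (adjusted p = 8.14e-04, 0.00322 and 0.00962), and none held with an estimated correlation (adjusted p = 0.391, 0.654 and 0.474).

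Altogether 395 genes differed at Day 4 in the edgeR fit, 309 higher and 86 lower in TKO, or 386 and 52 with library totals alone. Of the genes lower at Day 2, 8 were also lower at Day 4 (0.0400 for independent lists), namely Dnmt1, Dnmt3a, Dnmt3b, Dnmt3c, Tpi1, Aldoa, Pgk1 and Eif2s3y, and 2 of the higher ones were again higher (0.235 for independent lists). The knocked-out Dnmt1, Dnmt3a and Dnmt3b were lower on every day, so independent lists are no fair reference for them. The count was 246 without the batch term, 1270 with DESeq2, 1187 with limma on cell means and 231 with thinned cells. Leaving out any 1 of the 4 Day 4 sums gave 81 to 202 genes, the fewest without the WT sum of batch 2.

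Over the mean of the 4 days, 374 genes differed, 239 higher and 135 lower in TKO, or 555 and 81 with library totals alone. Leaving out 1 sum gave 125 (without the TKO Day 2 sum of batch 2) to 373, and dropping the batch term gave 181. The naive list had 5 up and 0 down of 27 (adjusted p = 5.10e-12, and 0.0649 with an estimated correlation). Glycolysis genes had 3 down of 18 (adjusted p = 2.16e-06, and 0.0741 with an estimated correlation) and stress genes 2 up of 20 (adjusted p = 7.53e-06, and 0.0242 with an estimated correlation). The p53 targets had 2 up of 19 (camera adjusted p = 1.77e-08, and 0.151 with an estimated correlation). Germline and primitive endoderm genes were placed higher, and formative and G2 and M phase genes lower (adjusted p = 1.195e-04, 0.00248, 0.0104 and 0.0223). None held with an estimated correlation (adjusted p = 0.1115, 0.0567, 0.350 and 0.743). The methylation machinery, with the knocked-out genes, was lower (adjusted p = 2.91e-24, and 0.00808 with an estimated correlation). Each batch alone called 3 genes. The difference between the time courses was tested as an interaction, and 25 genes passed over all days. At Day 4 relative to Day 0, 130 genes differed between the genotypes, 115 of them in the direction of higher TKO. Arc, an immediate early gene of neurons (chromosome 15, 74669083 to 74672570), stood at 33.4 ± 9.81 CPM in WT and 32.8 ± 7.66 CPM in TKO at Day 0 and at 23.5 ± 5.97 and 65.8 ± 11.3 CPM at Day 4 (adjusted p = 0.00750). The interaction count was 0 without the WT Day 4 sum of batch 2, and 973 with DESeq2; 2357 genes had an unadjusted p under 0.05 in the full fit.

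The position of single cells between the naive and the formative list was lower in TKO. Averaged over days and batches the score was -2.24 in TKO and -1.75 in WT, a difference of -0.49 (SD 0.34 over 8 day-by-batch pairs), lower in 8 of 8 pairs (exact sign-flip p = 0.00781, the smallest this test can give). By day, the differences in batches 1 and 2 were -0.29 and -0.00 at Day 0, -0.18 and -0.26 at Day 1, -0.82 and -0.76 at Day 2, and -0.73 and -0.88 at Day 4. The spread of the score between cells differed by 0.07 (exact sign-flip p = 0.273), and was past the threshold with unthinned cells (0.14, exact sign-flip p = 0.0312). Assigned to WT days, 82.8% of TKO cells of Day 2 matched their own day and 14 of 87 (16.1%, Wilson interval 9.83 to 25.2) matched Day 1, against 95.5% and 4 of 89 (4.49%, 1.76 to 11.0) in WT. At Day 4, 75 of 81 TKO cells (92.6%, 84.8 to 96.6) matched their own day and 4 matched Day 2, against 91 of 93 (97.8%, 92.5 to 99.4) and 1 in WT. The mean assigned day differed by -0.0655 (SD 0.0820; exact sign-flip p = 0.0625); it was lower in TKO in 5 pairs and tied in 3, and with 3 ties the test cannot give a smaller p. At Day 4, cells held on average 13.0 and 12.9 germline genes in the 2 TKO batches and 8.43 and 10.0 in WT; over all days the difference was 0.975 (exact sign-flip p = 0.234). TKO cells had 119 more detected genes at equal reads (SD 66.9; higher in 8 of 8 pairs; exact sign-flip p = 0.00781), a difference of -16.4 once the ribosomal RNA gene CT010467.1 was left out.

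**Figure D3:**
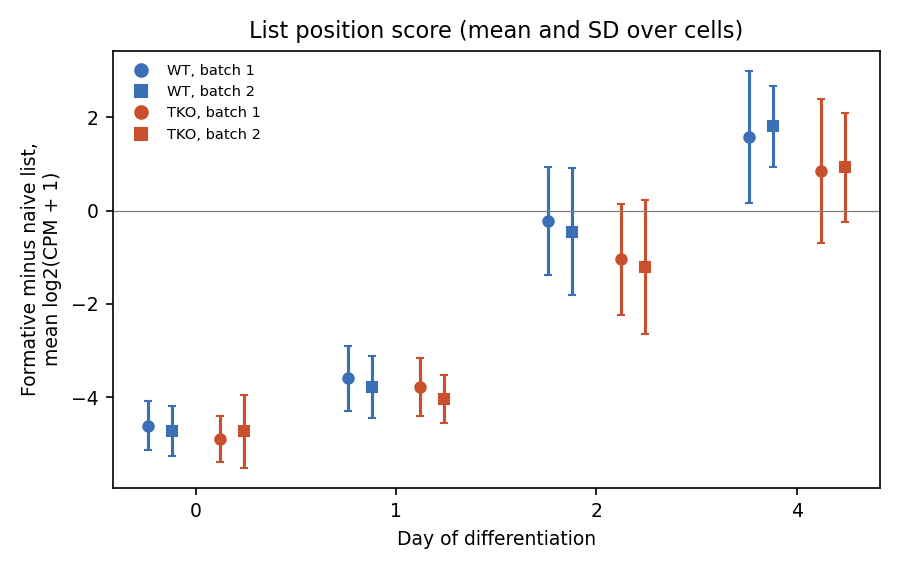
List position score (mean log2(CPM + 1) of formative minus naive genes) against the day of differentiation for each genotype and batch; points are means and bars SD over the kept cells, with WT in blue and TKO in red. The score rises with the day in both genotypes, and TKO means lie below WT means of the same batch, by -0.82 and -0.76 at Day 2.

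Chromosomes were compared to look for gains or losses in the cell lines. For each day and batch, the median log2 of TKO over WT for the genes of a chromosome was set against the median for the genes of all other chromosomes. Only genes with a mean of at least 5 CPM over the 16 sums were used. This difference ranged from -0.07 to 0.06 over the autosomes and the X chromosome. Among these, chromosome 7 alone was above the others in 8 of 8 pairs, with a mean difference of 0.0176 over 841 genes. Y-linked genes, 11 of them at that level, had a mean difference of -0.144 and were below the others in 7 of 8 pairs.

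**Figure D4:**
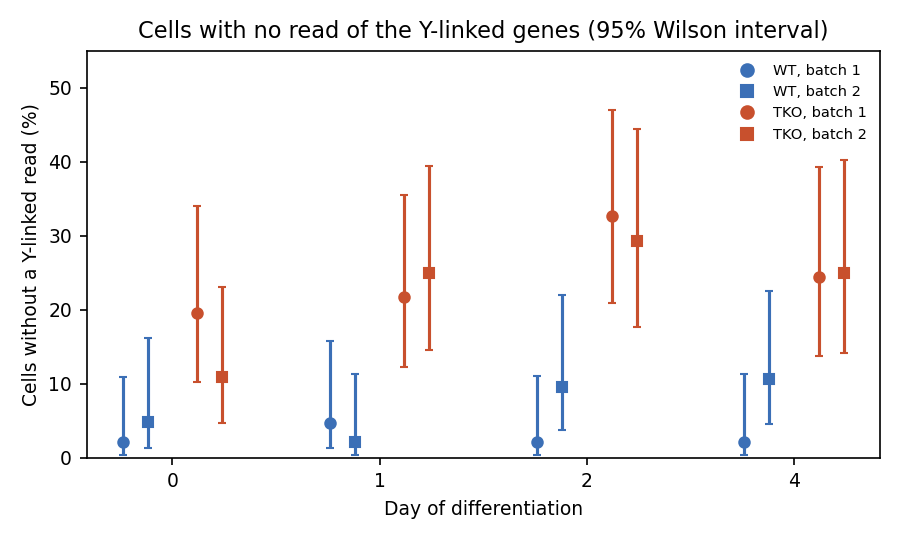
Share of kept cells without a read of 6 Y-linked genes (percent) against the day of differentiation, for each genotype and batch, with bars for the 95% Wilson interval; WT in blue and TKO in red, batch 1 as circles and batch 2 as squares. The share is higher in TKO in each day and batch, and over all days it is 23.5% in TKO and 4.74% in WT.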

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

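The tests of the number of genes above every WT sum (not of their share), of the weight of single cells, of depth and of exchanged genotypes were chosen only after the result was seen. The choices of lists, of the rule for named genes and of the alternatives, apart from leaving out CT010467.1, were made before the data were examined.

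The time course differed between TKO and WT for 25 genes, by the test of the interaction itself in edgeR. Arc passed with an adjusted p of 0.00750. Septin1, which was at 69.8 ± 13.9 CPM in WT and 63.7 ± 5.31 CPM in TKO at Day 0 and at 0.948 ± 0.191 and 6.05 ± 0.237 CPM at Day 4, had an adjusted p of 0.01004. Ror2 had an adjusted p of 0.0142, with 48.3 ± 3.38 and 48.0 ± 4.43 CPM at Day 0. Zfp640, annotated as a transcribed pseudogene, had an adjusted p of 0.0148, and was at 4.37 ± 0.663 CPM in WT and 13.9 ± 0.211 CPM in TKO at Day 4. Usp26 had an adjusted p of 0.0185, and fell in WT from 4.47 ± 0.956 CPM at Day 0 to no read at Day 4 while TKO went from 0.847 ± 0.0338 to 7.26 ± 4.85 CPM. Ifitm1 and Ushbp1 both had an adjusted p of 0.0228, with Ifitm1 at 20.1 ± 1.15 CPM in WT and 47.8 ± 1.04 CPM in TKO at Day 4. Rpl39l, a paralog of a ribosomal protein gene, had an adjusted p of 0.0234. Of these 8 genes, all were lost without the WT Day 4 sum of batch 2, when 0 genes passed. As lists, the germline genes and the X-linked homeobox and Xlr genes also differed in their change from Day 0 to Day 4, with camera adjusted p-values of 0.0242 and 0.0271 with an estimated correlation.

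Far more genes were past the threshold between TKO and WT at Day 4 than before. Genes with an unadjusted p under 0.05 in edgeR rose less steeply, at 2006, 1538, 2340 and 3279 on Days 0, 1, 2 and 4. Unequal weight of a few cells and unequal depth are argued against as the whole source. In limma on cell means, cells weigh the same. It called 1187 genes at Day 4 (246 of the 395 among them) against 51, 16 and 53 on the earlier days. With all cells thinned to 50000 reads, 231 were called at Day 4 (142 of the 395 among them) against 74 at Day 2. That gap was narrower than the 395 against 29 with all reads, but the thinned fit tested only 13513 genes. Day 4 sums held 21836616 to 27227568 reads. Day 2 sums held 32713606 to 40154165, and Day 1 sums 44532023 to 49453688. These reads argue against greater depth at Day 4 as a source of its larger count than on Days 1 and 2. Day 0 sums lay on both sides, at 16452604 and 19729038 reads in batch 1 and 37372167 and 38916043 in batch 2, so depth stays open there. A lag behind the WT time course may be part of the larger count at Day 4, and whether it is the whole stays open. Of the 309 raised genes, 234 stayed within the WT range. Of the 86 lowered genes, 16 lay over 1.5 times below every WT sum. The 6.47% of raised genes over 1.5 times above every WT sum met the bound of 10% set beforehand for a lag. Among the 300 genes most raised in 1 batch, 77.3% were higher at WT Day 2 than Day 4 in the other. The share over all 11348 genes at a mean of 5 CPM or more was 53.2%, which is no matched reference. The WT Day 4 level enters both sides of this comparison, though from different batches. Genes low at WT Day 4 in both batches are thereby favoured, with or without a lag. The slopes that follow share this limit. Genes falling in WT had slopes of 0.238 and 0.266. Genes that rise late in WT had slopes of 0.0393 and 0.0663. Both fell short of the bound set beforehand for a lag. They lay on either side of the bound of 0.05 for no lag, so neither prediction was met. The raised genes over 1.5 times above every WT sum numbered 20, among them Grb10, Epb41l3 and H2-D1 (chosen after their values were seen). For these 20, lag and no lag cannot be told apart, because they had been picked as raised. Of the TKO cells of Day 4, 92.6% matched WT Day 4 best, genes that fail to fall for another reason would look like a lag, and a direct effect of lost methylation stays open as an untested hypothesis.

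Exchanging TKO and WT labels within day and batch tested whether chance gives the 374 genes of the mean over days. Only the real split, 1 of 100, gave as many, and the highest of the others gave 78. Exchanged splits put real genotype differences inside the groups, which widens the spread and can lower their counts. The exchange therefore cannot exclude chance as the source.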

How the results depend on the processing

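Leaving out CT010467.1 was an alternative chosen after the data were seen. Of 6618 checks of named genes under the alternatives, 6333 stayed on their side of the threshold, 252 lost the call and 33 gained it. A gene past the threshold in neither fit counts as staying whatever its sign, and 0 genes past it in both fits reversed. The cause was not tested except where stated.

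TKO against WT at Day 0 gave 2 genes with library totals alone, 22 without a filter on low counts, 14 with at least 5 CPM in 2 sums, 301 with DESeq2 and 51 with limma on cell means. Day 1 gave 125 with DESeq2, 5 with thinned cells and 16 with limma. Day 2 gave 59 without the filter, 52 with at least 5 CPM, 519 with DESeq2, 18 with no replicate block, 74 with thinned cells and 53 with limma. Day 4 gave 1270 with DESeq2, 246 with no replicate block, 231 with thinned cells and 1187 with limma. The mean of the days gave 636 with library totals alone, 669 with at least 5 CPM, 1446 with DESeq2, 181 with no replicate block, 247 with thinned cells, and 3 with batch 1 alone and 3 with batch 2 alone, fits of fewer sums. WT at Day 4 against Day 0 gave 5117 with thinned cells, which hold fewer reads. The test of the time courses gave 122 without the filter, 83 with at least 5 CPM, 973 with DESeq2, 60 with thinned cells and 313 with limma. DESeq2 also gave more false calls on simulated data. In edgeR without the batch block, the spread between batches stays in the error.

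With each sum left out in turn, the lone sum of that group is assumed to vary like the other groups. The counts ranged from 1 to 8 at Day 0 (1 without TKO Day 0 batch 2), 2 to 6 at Day 1, 3 to 8 at Day 2, 81 to 202 at Day 4, 125 to 373 for the mean of the days (125 without TKO Day 2 batch 2), 5516 to 6049 for WT Day 4 against Day 0, 5630 to 6280 for TKO, 7704 to 8599 over any day in WT, 7862 to 8787 in TKO, and 0 to 30 for the difference of time courses (0 without WT Day 4 batch 2).

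The list position score difference was -0.50 with batch 1 alone and -0.48 with batch 2 alone, where 4 pairs cannot give an exact p below 0.125, and -0.49 with no replicate block (permutation p = 0.696), which puts the days into the spread. The spread of the score passed at 100000 reads (0.118, exact p = 0.0469) and unthinned (0.137, exact p = 0.0312). The difference in genes detected per cell was 0.625 unthinned (exact p = 0.992), reversed to -16.4 without CT010467.1 (exact p = 0.672), and was 141 with batch 1 alone and 97.9 with batch 2 alone. Of the list tests, 22 passed with an estimated correlation.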

Other observations

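The test of Y-linked reads was chosen only after the result was seen, and leaving out CT010467.1 was added after the data were examined.

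Other gene groups also moved as WT cells left the naive state. Interferon and viral sensing genes had 9 up and 2 down of 18 at Day 4 (camera adjusted p = 0.0350, and 0.309 with an estimated correlation); Bst2, an antiviral membrane protein, rose by 3.29 ± 0.28 and the transcription factor Irf1 by 2.29 ± 0.23, while Oas1a changed by -5.07 ± 0.52 (n = 2). In TKO the list had 10 up and 1 down (adjusted p = 0.00638, and 0.149 with an estimated correlation), and between TKO and WT at Day 4 none was past the threshold, with Irf1 at 202 ± 6.29 and 188 ± 34.2 CPM. The primordial germ cell list had 2 up and 10 down of 15 in WT (adjusted p = 2.62e-04, and 0.140 with an estimated correlation), with the receptor Kit at -3.89 ± 0.26. Primitive endoderm genes had 6 up and 5 down of 20, trophoblast genes 2 up and 7 down of 19, mesendoderm genes 2 up and 3 down of 16, and neural genes 6 up and 5 down of 21, with Sox11 at 6.70 ± 0.77. The fibroblast list had 5 up and 2 down of 12, the p53 list 5 up and 4 down of 19, S phase genes 1 up and 6 down of 28, G2 and M phase genes 9 up and 1 down of 26, and stress genes 8 up and 7 down of 20. None of the tests of the last 9 lists passed in WT, G2 and M phase genes coming closest (adjusted p = 0.0543). No cell of any of the 8 groups had at least 4 two-cell-like genes at 10 CPM, and none of the 3 such genes tested was past the threshold between Day 4 and Day 0 in WT. By the same measure, at least 4 fibroblast genes were held by 8 of 87 TKO and 0 of 89 WT cells at Day 2 and by 12 of 81 and 23 of 93 at Day 4, and at least 4 neural genes by 65 of 81 TKO and 49 of 93 WT cells at Day 4.

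Y-linked transcripts were lower in TKO. Reads of 6 Y-linked genes, Eif2s3y among them, were absent from 81 of 345 TKO cells (23.5%, Wilson interval 19.3 to 28.2) and 17 of 359 WT cells (4.74%, 2.98 to 7.45), a difference of 18.8 percentage points (SD 7.11), higher in 8 of 8 pairs (exact sign-flip p = 0.00781). A lower level in every TKO cell as the whole account is argued against. In WT cells, 50 sets of autosomal genes at the same mean level were unseen in at most 6.69%, against 23.5% here. The sets were matched by mean level alone. Their median was 3.06%, below the 4.74% of WT cells for Y-linked genes at a higher level. Y-linked reads had means of 51.1 CPM in TKO and 104 CPM in WT, with medians of 28.2 and 96.1 CPM. Whether TKO cells with Y-linked reads also had a lower level was not tested. Loss of the Y chromosome in part of the TKO line is a candidate explanation, a hypothesis that only DNA could test. Each genotype is 1 line in these data, so the history of the clone and the knockout are confounded.

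The larger number of genes detected in TKO cells went with fewer reads on CT010467.1, annotated as ribosomal RNA, which took 22.2% of the reads of the median TKO cell and 25.8% in WT. With it left out before thinning, the difference of 119 genes became -16.4, so a lower share of ribosomal reads may account for it. Whether the share reflects the cells or the libraries was not tested, and a biological difference between the genotypes stays open.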
